A study of Homo sapiens with 8 samples.

How the data were processed

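Total RNA of MCF-7 and MDA-MB-231 cells was made into libraries with a kit that depletes ribosomal RNA, and sequenced by the submitters. Per the labels, the authors used bcl2fastq 2.17 to make reads, Trim Galore 0.4.5 to trim them, STAR 2.6.1d to align them to GRCh38 and featureCounts 1.6.3 to count them per RefSeq gene symbol. Strand and multi-mapping settings and the annotation release were not given in the sources used here. The deposited files hold raw counts, 1 table per cell line, with 44608 genes each; all values were checked to be whole numbers. Positions came from the NCBI RefSeq annotation of GRCh38, matched by symbol for 35597 genes and by synonym for 846, while 8165 had no match.

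The columns are not named as the samples are. Columns named control were taken as wild type and the other 2 columns of each table as knockout, since the labels give each table those groups alone. The MDA-MB-231 columns carry 1 and 2, as do the replicate and clone labels, and the MCF-7 columns do not. The libraries were called A and B in column order, which is 1 and 2 in MDA-MB-231, and no pairing was assumed. All 8 columns were used. Library totals ranged from 20075336 to 34453574 counts. Replicate libraries were checked for duplication: over genes with a mean of at least 20 counts, chi-square per degree of freedom was between 2.61 and 5.47, above the value near 1 of split libraries. Counting intervals (95%, exact binomial) and floors (3 counts over the group) cover counting error only.

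Each line was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood test, 2 libraries against 2), and Benjamini-Hochberg adjusted p under 0.05 was called. The biological coefficient of variation was 3.44% in MCF-7 and 4.37% in MDA-MB-231. The difference between the lines was the interaction term of a fit over all 8 libraries. Fold changes are knockout over wild type, and CPM are scaled by TMM. TMM and DESeq2 size factors both take most genes to be unchanged or their changes to balance. Agreement between them therefore does not test that scale. Overlaps between the lines were set against the product of the list sizes over the number of genes tested in both, with a one-sided Fisher's exact test. Genes are not independent, so its p describes the lists only. The 37 gene lists were fixed before the data were examined, and 36 had at least 3 tested genes; the list of mitochondrially encoded genes was not tested because those genes are missing from the tables. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the lists) and, as alternatives, with an estimated correlation and with fry. Where a single number stands beside a list member, it is the log2 fold change in that line.

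Genes were named by a rule fixed before the data were examined: EGR1 and EZH2; in each line the 10 called genes with the largest rise and the 10 with the largest fall that reached 2 CPM in the higher group and had both knockout libraries on the same side of both wild-type libraries; the 10 genes with the largest change in a common direction; the 5 largest differences between the lines each way; and list members that passed, led by those with the smallest p. Symbols of unnamed loci, small RNAs, antisense transcripts and numbered pseudogenes were passed over. The rule read symbols as spelled in the counts, so ZNF788P and C6orf223 were kept.

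Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 test, limma voom with group weights, 1 fit over all libraries, a replicate block (run in MDA-MB-231 alone), an adjusted p of 0.01 for the overlap, the other list tests and leaving out each library. The tests were also run on simulated counts drawn from the fitted means and spreads with known changes in 200 genes. In MCF-7 edgeR recovered 35.4% of genes changed 1.25-fold, 77.6% at 1.5-fold and 94% at 4-fold, with 8 false calls. In MDA-MB-231 it recovered 46.9%, 68% and 98.0%, with 14 false calls. Far fewer genes changed in the simulations than were called in the data, so these numbers do not give the recovery or false calls of the reported tests.

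Regional tests were added after the data were examined. Genes with a mean of at least 2 CPM were placed in windows of 10 Mb, windows with at least 10 genes were kept, and each window's median log2 fold change was compared with 10000 shuffles of genes over positions. On simulated data, a shift of −0.5 was found in 7 of 12 windows in MCF-7 and in 12 of 12 in MDA-MB-231, and a shift of −0.25 in 0 and 10. Genes with a start within 10 Mb of EGR1 or EZH2 were their neighbours, with bootstrap intervals of the median (10000 draws). For the sterol synthesis list, a trend on GC content and transcript length (50 rank bins, GENCODE transcripts) or the median of the other genes of the window was removed, and the list median was compared with 10000 random lists of matched expression. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.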

Results

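Total RNA was sequenced from 8 cultures of 2 human breast cancer cell lines, MCF-7 and MDA-MB-231. MCF-7 is an oestrogen receptor-positive luminal line, and MDA-MB-231 is a triple-negative line with mesenchymal features. In each line wild-type cells were compared with puromycin-selected cells in which CRISPR-Cas9, a guided nuclease, had removed a silencer of 1780 bp; a silencer is a stretch of DNA that lowers the transcription of a gene it acts on. The labels gave neither the position of the silencer nor its target gene. Each of the 4 groups held 2 libraries, called A and B here in the order of the deposited columns. The libraries held 20075336 and 28725927 counts in MCF-7 wild type, 25196801 and 24165860 in MCF-7 knockout, 31063291 and 28561647 in MDA-MB-231 wild type, and 27430847 and 34453574 in MDA-MB-231 knockout. Both knockout columns of a table shared 1 name stem, while the labels called the samples clone 1 and clone 2, so whether the libraries came from separate clones was not settled by the files. The p-values below measure only the spread between the libraries of a group.

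The series title names EGR1 and EZH2, and the first question was how the deletion changed each of them. EGR1, an immediate early zinc-finger transcription factor (chromosome 5, 138465479 to 138469303, GRCh38), rose in both knockouts. In MCF-7 it went from 17.8 ± 0.346 to 37.0 ± 2.16 CPM (counts scaled to a common library size, mean ± SD, n = 2), a log2 fold change of 1.06 (SE 0.083, adjusted p = 1.59e-31). In MDA-MB-231 it went from 38.6 ± 0.142 to 102 ± 2.49 CPM, a log2 fold change of 1.40 (SE 0.060, adjusted p = 1.71e-14). The rise was larger in MDA-MB-231 by 0.33 on the log2 scale (interaction, adjusted p = 0.00451). EZH2, the methyltransferase subunit of Polycomb repressive complex 2 (PRC2; chromosome 7, 148807383 to 148884291), moved in opposite directions. It rose in MCF-7 from 105 ± 4.78 to 128 ± 1.99 CPM, 1.22-fold (log2 0.28, SE 0.051, adjusted p = 9.63e-08). It fell in MDA-MB-231 from 96.4 ± 3.54 to 78.3 ± 1.40 CPM, a log2 fold change of −0.30 (SE 0.056, adjusted p = 0.00018). The difference between the lines was −0.60 (interaction, adjusted p = 8.24e-10).

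**Figure D1:**
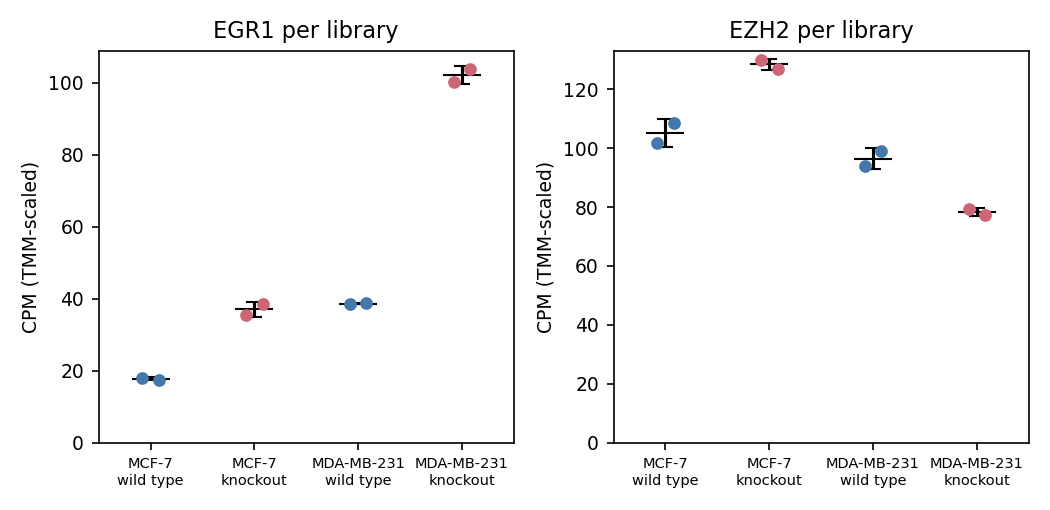
EGR1 and EZH2 expression in CPM (TMM-scaled, linear axis from 0) in each library, with wild type in blue and knockout in red; horizontal lines are group means and bars the SD of 2 libraries. EGR1 is higher in every knockout library than in either wild-type library of its line, while EZH2 is higher in the MCF-7 knockout and lower in the MDA-MB-231 knockout.

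Genes lying near EZH2 moved with it. In MDA-MB-231 the 88 expressed genes (mean of at least 2 CPM) within 10 Mb of EZH2 had a median log2 fold change of −0.23 (95% bootstrap interval −0.28 to −0.18), and 89.8% of them had a negative value. In MCF-7 the 100 expressed genes within that distance had a median of 0.38 (interval 0.21 to 0.50), and 79% had a positive value. EZH2 thus lay 0.07 below its neighbours' median in MDA-MB-231 and 0.09 below it in MCF-7. EGR1 rose more than most of its region. Its 132 expressed neighbours in MCF-7 had a median of 0.21 and its 108 neighbours in MDA-MB-231 a median of 0.06. EGR1 exceeded these by 0.85 and 1.34 and lay above 93.2% and 97.2% of its neighbours. DNA copy number was not measured in these samples.

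**Figure D2:**
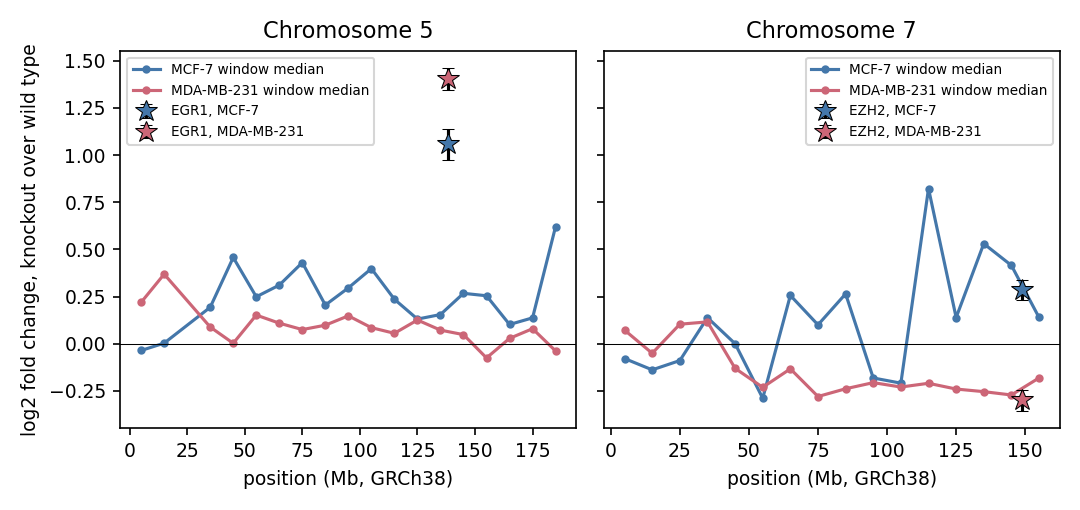
Median log2 fold change (knockout over wild type) of expressed genes in 10 Mb windows along chromosomes 5 and 7, with MCF-7 in blue and MDA-MB-231 in red; stars are EGR1 and EZH2 and bars their SE. Both EGR1 stars (1.06 and 1.40) lie above all window medians of chromosome 5, while both EZH2 stars (0.28 and −0.30) lie near the windows around them.

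In MCF-7 most tested genes differed between knockout and wild type: of 16292 genes, 5659 (34.7%) were higher and 5703 (35%) lower in the knockout (edgeR, adjusted p under 0.05). Scaling by TMM centres the fold changes, and no test of that scale was possible from these counts. The near-equal shares, and the direction of small changes such as EZH2 at 0.28 in MCF-7, depend on it. Changes of at least 2-fold were seen in 1716 higher and 1514 lower genes. The log2 differences between group means had an SD of 0.94 over genes, against 0.31 between the wild-type libraries and 0.29 between the knockout libraries. Among genes that reached 2 CPM in the higher group, the deepest losses included TGM2, a transglutaminase that cross-links proteins, which went from 92.6 ± 2.79 CPM to 3 counts over both knockout libraries (ratio 1533, 95% counting interval 524 to 7435). DIO2, the deiodinase that activates thyroid hormone, fell 159-fold (809 to 5 counts), and the potassium channel gene KCNK2 fell 121-fold (500 to 4 counts). So few knockout counts leave the size of both folds uncertain. The histone deacetylase gene HDAC9, ZNF804A and BPIFA1 had no counts in the knockout and were at least 66.6-fold, 49-fold and 36.9-fold lower, taking 3 counts over the group as the floor. GPRIN3 (ratio 348, interval 62.0 to 13771), the receptor gene GLP2R (203, 36 to 8050), RUNX1T1 (167, 29.5 to 6620) and VIL1, which encodes the actin-bundling protein villin (166, 45.5 to 1373), kept 1 or 2 counts.

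The genes that gained most in MCF-7, under the same limit of 2 CPM, included several zinc-finger genes. ZNF788P, whose symbol is that of a pseudogene, ZNF300, ZNF415 and ZNF99 were 43.8-fold, 33.4-fold, 27.1-fold and 19.05-fold higher in the knockout. Their wild-type counts were 6, 8, 31 and 5, and wild-type values varied for ZNF300 (0.149 ± 0.139 CPM) and ZNF99 (0.096 ± 0.064 CPM), so these folds are uncertain. ZNF608 went from 2 to 101 counts (ratio 48.8, 95% counting interval 13.2 to 409). The forkhead factor gene FOXN4 went from 1 to 124 counts (ratio 120, interval 21.1 to 4772). GABRP, a GABA receptor subunit, rose 31.9-fold, and SERPING1, the inhibitor of complement component C1, rose 28.8-fold (4 to 126 counts). The mitochondrial folate enzyme gene ALDH1L2 went from 0.902 ± 0.079 to 27.9 ± 1.02 CPM (log2 4.96). DMGDH, another mitochondrial one-carbon enzyme gene, rose 23.2-fold (7 to 174 counts). The rule for naming passed over 5 higher and 1 lower transcript with unnamed or non-coding symbols, and 1 higher in MDA-MB-231.

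Among the gene lists, sterol and fatty acid synthesis fell as a group in MCF-7. Of 33 members, 29 fell and 3 rose (camera adjusted p = 9.77e-11; adjusted p = 0.52 with an estimated correlation). SCD, the fatty acid desaturase, went from 896 ± 24.0 to 362 ± 2.64 CPM, and the sterol reductase gene DHCR7 changed by −1.31, LDLR by −1.34 and INSIG1 by −1.21. Proliferation genes were lower too. Of 48 DNA replication and S phase genes 39 fell and 3 rose (adjusted p = 2.19e-09), among them the thymidine kinase gene TK1 (−1.58), UHRF1 (−1.28), the cyclin gene CCNE1 (−2.22) and MCM4 (−0.95). Of 50 mitosis and G2 genes 38 fell and 5 rose (adjusted p = 6.56e-06), with PLK1 at −1.18 and FOXM1 at −1.19. Of 40 ribosome biogenesis and MYC target genes 27 fell and 4 rose (adjusted p = 0.000952), with NOP2 at −1.33. Each of these lists had an adjusted p of 0.52 with an estimated correlation. Adjusted over the list alone, the counts were the same except that 40 replication genes fell.

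Redox and energy metabolism genes also fell in MCF-7. Of 29 oxidative stress (NRF2) genes 24 fell and 2 rose (adjusted p = 2.48e-06; adjusted p = 0.52 with an estimated correlation). The quinone reductase NQO1 went from 942 ± 23.5 to 289 ± 3.27 CPM, GPX2 changed by −2.10 and HMOX1 by −1.44, while the cystine transporter gene SLC7A11 rose by 2.07. Of 72 nuclear respiratory chain genes 49 fell and 11 rose (adjusted p = 0.0014; 0.675 as adjusted p with an estimated correlation). Of 38 hypoxia and glycolysis genes 23 fell and 8 rose (adjusted p = 0.0165; 0.569 as adjusted p with an estimated correlation). The glycolytic genes PGK1 (−1.42) and GAPDH (−0.99) fell, while VEGFA (1.04) and DDIT4 (1.77) rose. Of 31 extracellular proteases and inhibitors 16 fell and 2 rose (adjusted p = 0.005; 0.52 as adjusted p with an estimated correlation), and the members with the smallest p values included the protease inhibitor genes TIMP3, at 73.9 ± 0.581 against 2.89 ± 0.488 CPM, and TIMP2 (−2.05). Adjusted over the list alone, 12 respiratory chain genes and 9 hypoxia genes rose, and the other counts were the same. PGK1, G6PD (−1.11), COX7B (−1.32), EBP (−1.76) and KIF4A (−1.55) lie on chromosome X, where 391 expressed genes had a median of −0.65. GAPDH and FOXM1 lie in the first 40 Mb of chromosome 12, where 153 genes had a median of −0.52. With the medians of 10 Mb windows subtracted, the hypoxia list had an adjusted p of 0.0854.

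The lists that rose in MCF-7 were amino acid stress, luminal and ribosomal protein genes. Of 35 unfolded protein and amino acid stress genes 24 rose and 9 fell (adjusted p = 2.55e-07; adjusted p = 0.52 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, went from 47.3 ± 1.26 to 303 ± 13.2 CPM, the amino acid transporter gene SLC7A5 rose by 2.18 on the log2 scale, the asparagine synthetase gene ASNS by 2.33 and CHAC1 by 2.43. Of 27 luminal epithelial markers 17 rose and 8 fell (adjusted p = 0.000952; 0.52 as adjusted p with an estimated correlation), with TFF3 at 2.51, the prolactin receptor gene PRLR at 1.6, ERBB3 at 1.07 and the oestrogen receptor gene ESR1 at −0.42. Of 78 cytosolic ribosomal protein genes 49 rose and 16 fell (adjusted p = 0.000551; 0.692 as adjusted p with an estimated correlation), led by RPL10A (0.67) and RPL4 (0.61). Of 18 genes around EGR1 on 5q31, EGR1 included, 11 rose and 2 fell (adjusted p = 0.022; 0.52 as adjusted p with an estimated correlation). Adjusted over the list alone, 51 ribosomal protein genes rose and the other counts were the same. The ribosomal protein list did not pass with fry, which asks whether a list moves at all (adjusted p = 0.0656). The EGR1 neighbourhood and respiratory chain lists each had an adjusted p of 0.0507 without wild-type library A, and the EGR1 neighbourhood had 0.365 with the medians of 10 Mb windows subtracted.

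The 36 EGR family and immediate early genes did not pass as a list in MCF-7 (adjusted p = 0.0917), although 19 rose and 9 fell. EGR3 rose by 2.95, FOS by 1.99 and NAB2, a corepressor of EGR proteins, by 1.19, while PHLDA1 fell by 3.32 on the log2 scale. Of 35 oestrogen receptor targets 20 rose and 14 fell (adjusted p = 0.0997), with GREB1 at 1.6, AREG at 1.99, CA12 at −2.92 and CCN5 at −5.69. Of 12 PRC2 subunits 3 rose and 5 fell (adjusted p = 0.324); RBBP7, on chromosome X, changed by −1.38, EED by −0.67 and EZH1 by 0.50. Of 24 classical Polycomb-repressed genes 5 rose and 13 fell (adjusted p = 0.0917; 7 rose adjusted over the list alone), and of 21 genes around EZH2 on 7q36 15 rose and 4 fell (adjusted p = 0.117). The remaining lists that did not pass in MCF-7 were haematopoietic markers (adjusted p = 0.0643), NF-kappaB genes (0.0916), mesenchymal and basal markers (0.178), growth factor receptors and ligands (0.178), interferon-stimulated genes (0.247), TGF-beta targets (0.252), homologous recombination genes (0.272), integrins and laminins (0.300), endothelial and fibroblast markers (0.389) and PRC1 subunits (0.518). They further included p53 targets (0.626), HLA genes (0.686), HOX genes (0.686), replication-dependent histones (0.720), cancer-testis antigens (0.746), collagens (0.799), apoptosis regulators (0.859), YAP and TEAD targets (0.859) and Wnt and Notch targets (0.859). Interferon genes had a positive median (0.08) and a negative mean (−0.04, which included PSMB8 with 1 count in the knockout), and Wnt and Notch targets had a negative median (−0.20) and mean (−0.10), while the test pointed up for both.

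In MDA-MB-231 fewer genes passed: of 15270 tested genes, 2889 (18.9%) were higher and 2951 (19.3%) lower in the knockout. Changes of at least 2-fold were seen in 302 higher and 349 lower genes. The SD of the log2 differences between group means was 0.49, against 0.31 and 0.29 between libraries of a group. The genes that gained most among those that reached 2 CPM included several cell-surface genes, a group that was not tested as a list. TSPAN7, a tetraspanin, went from 2 to 131 counts (ratio 64.0, 95% counting interval 17.4 to 534), and the cadherin genes CDH18 and CDH12 rose 24.1-fold and 9.74-fold. CDH12 varied between the wild-type libraries (0.456 ± 0.298 CPM), so its fold depends on the library used. The receptor tyrosine kinase gene EPHA3 rose 16.4-fold, the GABA receptor gene GABRB3 14.9-fold (8 to 127 counts) and the basement membrane collagen gene COL4A5 12.2-fold. NAP1L3, a nucleosome assembly protein gene, went from 0.651 ± 0.021 to 14.9 ± 0.070 CPM, and CAPN6, RNF128 and the non-coding LNCOG rose 11.7-fold, 10.6-fold and 8.10-fold. TSPAN7, NAP1L3, COL4A5, CAPN6 and RNF128 lie on chromosome X, where 379 expressed genes had a median of 0.08.

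Among genes that reached 2 CPM in wild type, those that fell most in MDA-MB-231 were the cancer-testis antigen gene MAGEA12 (39.3-fold, 201 to 5 counts) and FGF13 (24.6 ± 0.567 to 0.729 ± 0.159 CPM, 34.1-fold). Both lie on chromosome X, as some of the genes that gained most do. EPB41L3, a membrane skeleton gene, fell 31.3-fold (161 to 5 counts) and C6orf223 15.1-fold (152 to 10 counts). The current symbol of C6orf223 is LINC03040, that of a non-coding RNA. The transporter gene ABCA8, LZTS1, the adhesion molecule genes MXRA8 and IGSF9, ZNF43 and the G protein subunit gene GNB3 fell between 7.21-fold and 4.8-fold. LZTS1 and ZNF43 varied between the knockout libraries (0.410 ± 0.248 and 0.389 ± 0.239 CPM), so their folds depend on the library used. Without knockout library A 1893 genes were higher and 1930 lower.

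Sterol and fatty acid synthesis fell in MDA-MB-231 as well: 31 of 33 members fell and none rose (adjusted p = 3.03e-35; adjusted p = 0.285 with an estimated correlation). FADS2 went from 409 ± 10.0 to 201 ± 3.89 CPM and SCD from 944 ± 33.2 to 482 ± 14.2 CPM, INSIG1 changed by −1.02 and HMGCS1, the HMG-CoA synthase gene, by −1.02. Of 50 mitosis and G2 genes 23 fell and 2 rose (adjusted p = 0.000204; 0.549 as adjusted p with an estimated correlation), with ASPM at −0.68, GTSE1 at −0.53 and KIF14 at −0.56. ASPM and KIF14 lie on chromosome 1 beyond 140 Mb, where 519 expressed genes had a median of −0.24. Of 30 NF-kappaB and inflammatory genes 11 fell and 5 rose (adjusted p = 0.00809; 0.549 as adjusted p with an estimated correlation), with the chemokine gene CCL2 at −1.23, IL11 at −0.56 and IL1B at 1.27. Of 19 genes around EZH2 on 7q36, EZH2 included, 12 fell and none rose (adjusted p = 0.000646; 0.48 as adjusted p with an estimated correlation, and 0.771 with the medians of 10 Mb windows subtracted). Adjusted over the list alone, 13 NF-kappaB genes and 13 genes around EZH2 fell and the other counts were the same. The NF-kappaB list did not pass with fry (adjusted p = 0.0849).

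**Figure D3:**
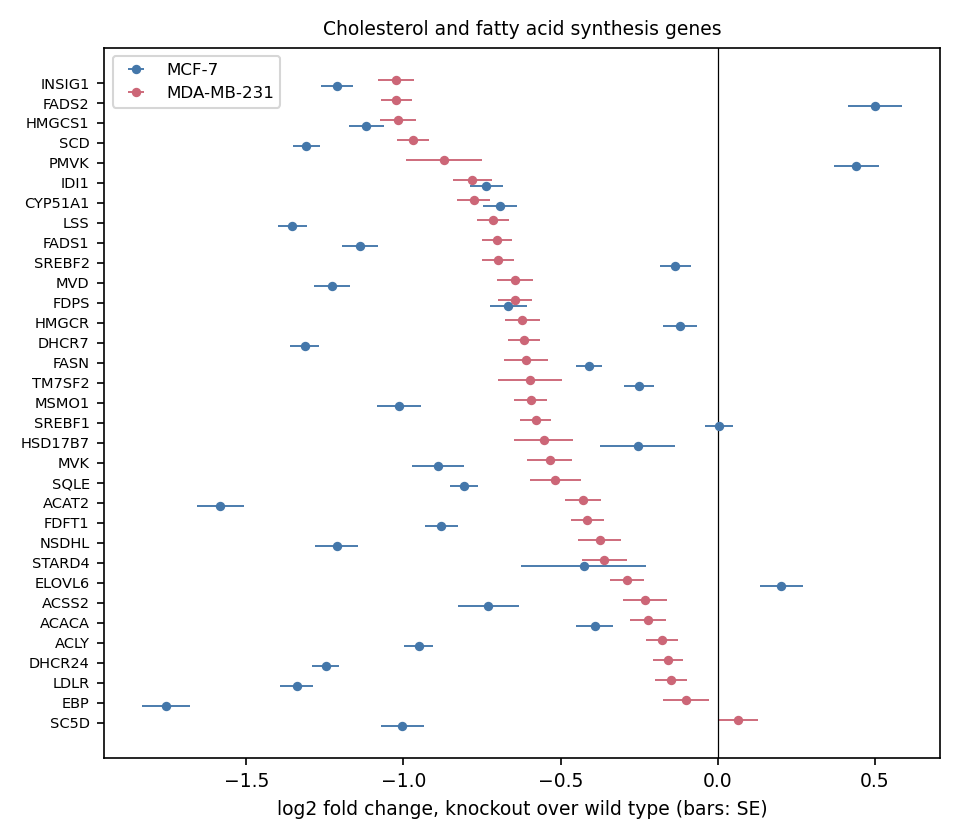
Log2 fold change (knockout over wild type, bars SE, n = 2 libraries per group) of the 33 sterol and fatty acid synthesis genes, with MCF-7 in blue and MDA-MB-231 in red. Of these genes 29 fell in MCF-7 and 31 in MDA-MB-231, while FADS2, PMVK and ELOVL6 rose in MCF-7.

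Immediate early genes rose as a list in MDA-MB-231. Of 36 EGR family and immediate early genes, EGR1 included, 16 rose and 5 fell (adjusted p = 0.000229; 0.48 as adjusted p with an estimated correlation). EGR2 rose by 1.30, ATF3 by 1.44, FOSB by 1.21 and CCN1 by 0.72, while FOS had a value of 0.14 (adjusted p = 0.507). Of 36 unfolded protein and amino acid stress genes 20 rose and 4 fell (adjusted p = 0.000229; 0.48 as adjusted p with an estimated correlation), with DDIT3 at 1.24, CHAC1 at 0.82 and PPP1R15A at 0.54. Of 34 p53 targets 12 rose and 2 fell (adjusted p = 0.00648, and 0.48 as adjusted p with an estimated correlation), with GADD45A at 1.23, GDF15 at 1.30 and the cell cycle inhibitor gene CDKN1A at 0.72. In camera on log2 CPM of the 31 p53 targets with a 10 Mb window the adjusted p was 0.0891, and 0.274 with window medians subtracted. Of 37 proteases and inhibitors 19 rose and 10 fell (adjusted p = 0.000391; 0.511 as adjusted p with an estimated correlation), with TIMP3 at 1.06 and ADAMTS12 at 2.73. Of 41 hypoxia and glycolysis genes 22 rose and 5 fell (adjusted p = 0.000459; 0.611 as adjusted p with an estimated correlation), with HK2 at 0.71 and LDHA at 0.39. Adjusted over the list alone, 17 immediate early genes rose and 6 fell, 21 stress genes rose and 5 fell, 4 p53 targets fell, 21 proteases and inhibitors rose, and the other counts were the same. Proteases and inhibitors (adjusted p = 0.0537) and hypoxia and glycolysis genes (0.111) did not pass with fry.

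In MDA-MB-231 5 further lists passed upward, with larger adjusted p values. Of 78 ribosomal protein genes 26 rose and 3 fell (adjusted p = 0.0126; 0.831 as adjusted p with an estimated correlation), with RPL24 at 0.43. Of 21 classical Polycomb-repressed genes 11 rose and 6 fell (camera adjusted p = 0.0261, and 0.511 as adjusted p with an estimated correlation). Members included TIMP3 again, GATA6 at 0.82, ISL1 at 3.45 and NKX2-1 at −0.75. ISL1 did not meet the CPM or the library condition set for the genes that gained most, so the size of its rise is uncertain. Of 22 HLA and antigen presentation genes 8 rose and 3 fell (adjusted p = 0.0298; 0.511 as adjusted p with an estimated correlation), with HLA-B at 0.44 and HLA-C at 0.45. Of 25 YAP and TEAD targets 9 rose and 7 fell (adjusted p = 0.0422), and of 21 luminal markers 7 rose and 5 fell (adjusted p = 0.0494); each had an adjusted p of 0.611 with an estimated correlation. F3 changed by 0.79 and TGFB2 by −0.77, and the luminal keratin genes KRT8 and KRT18 rose by 0.70 and 0.75. Adjusted over the list alone, 10 HLA genes rose and the other counts were the same. Ribosomal proteins (adjusted p = 0.401), luminal markers (0.0919) and YAP and TEAD targets (0.0919) did not pass with fry. With a replicate block the camera adjusted p was 0.0671 for luminal markers and 0.0792 for YAP and TEAD targets. In camera on log2 CPM of genes with a 10 Mb window, it was 0.105 for classical Polycomb genes and 0.0916 for HLA genes. In that test it was 0.304 for YAP and TEAD targets and 0.0891 for luminal markers. Some of these calls depended on 1 library: the adjusted p was 0.613 for ribosomal proteins without wild-type library A, 0.0504 and 0.0640 for HLA genes without wild-type library B and knockout library A, just above 0.05 and 0.159 for YAP and TEAD targets without wild-type library A and knockout library B, and 0.160 and 0.0746 for luminal markers without wild-type library B and knockout library B.

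Polycomb subunits did not pass as lists in MDA-MB-231. Of 12 PRC2 subunits 4 rose and 2 fell (adjusted p = 0.879; 3 fell adjusted over the list alone), and PHF19 changed by −0.49; the median was 0.01 while the test pointed down. PRC1 subunits had an adjusted p of 0.662 and HOX genes of 0.321, with HOXB9 at 1.13. The other lists that did not pass were ribosome biogenesis genes (adjusted p = 0.0896), interferon-stimulated genes (0.111), cancer-testis antigens (0.123), respiratory chain genes (0.132), DNA replication genes (0.138), haematopoietic markers (0.138), oestrogen receptor targets (0.207), replication-dependent histones (0.234), homologous recombination genes (0.247) and endothelial and fibroblast markers (0.247). They further included TGF-beta targets (0.283), the EGR1 neighbourhood (0.285), collagens (0.410), NRF2 genes (0.727), integrins and laminins (0.767), growth factor receptors and ligands (0.771), apoptosis regulators (0.771), Wnt and Notch targets (0.800) and mesenchymal and basal markers (0.825). Collagens (median −0.15, mean 0.11), Wnt and Notch targets (−0.07, 0.03) and growth factor genes (−0.03, 0.01) had means of the opposite sign to their medians and tests, and NRF2 genes had a median of −0.02 while the test pointed up.

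The comparison between the lines asked whether the deletion changed the same genes in both. Over the 13615 genes tested in both lines the log2 fold changes did not go together (across genes, Pearson −0.013 and Spearman −0.013; genes are not independent replicates). Of the genes called in both lines, 897 were higher in both, against 890.8 expected of independent lists (one-sided Fisher's exact test, p = 0.396), but this depended on the setting, with 576 against 527.4 in DESeq2 (p = 0.00412, Fisher's exact test) and 811 against 755.3 without MDA-MB-231 wild-type library A (p = 0.00356, same exact test). Another 1094 were lower in both, against 1022.1 expected (p = 0.000818, same exact test; p = 0.0869 without MDA-MB-231 wild-type library B). Opposite directions were seen in 2045 genes: 1109 fell in MCF-7 and rose in MDA-MB-231, against 978.6 expected (p = 3.18e-09, Fisher's exact test), and 936 did the reverse, against 930.4. The exact tests take genes as independent, while neighbouring genes shifted together, so their p-values describe the lists and do not show shared or opposed regulation. The number higher in both depended on the setting, with 576 against 527.4 expected in DESeq2 (p = 0.00412, Fisher's exact test). However, the share of genes called in both lines that had the same direction was 49.8% in DESeq2 and 49.3% in the main test. Among genes that reached 2 CPM in each line, the largest changes in a common direction included MUC5AC, a gel-forming mucin gene (−2.54 in MCF-7, −2.08 in MDA-MB-231), RAB3B, a vesicle GTPase gene (−2.16, −2.05), and the uroplakin gene UPK3B (−1.61, −1.53). The prostaglandin E synthase gene PTGES (−3.46, −1.36), the kynureninase gene KYNU (−2.94, −1.30), RASD1 (−3.20, −1.40) and the integrin gene ITGA10 (−1.50, −1.29) fell in both. The arrestin-like gene ARRDC4 (1.63, 1.57), ZNF558 (1.37, 2.18) and ZNF391 (1.28, 1.45) rose in both.

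**Figure D4:**
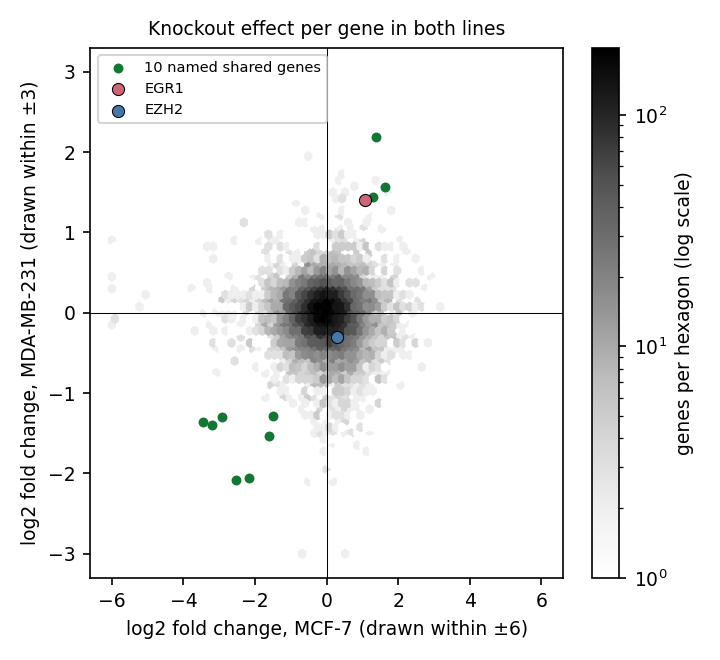
Log2 fold change of each gene tested in both lines, MCF-7 on the horizontal and MDA-MB-231 on the vertical axis, with shading for the number of genes per hexagon on a log scale; values are drawn within the limits given on the axes. The cloud has no slope (Pearson −0.013 across genes), and EGR1 lies in the upper right with 3 of the 10 marked shared genes.

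A direct test of the difference between the lines called 8895 of 18082 genes: the log2 fold change was more positive in MDA-MB-231 for 4571 and more negative there for 4324, whatever the size of the effect in either line. Among genes that reached 2 CPM in a group, most of the largest differences were in genes lost in 1 line alone. TGM2 had 3 counts in the MCF-7 knockout but went from 147 ± 5.42 to 271 ± 6.78 CPM in MDA-MB-231 (adjusted p = 4.22e-56 for the difference). HDAC9, ZNF804A and SEC14L4 had no counts in the MCF-7 knockout and 817, 666 and 344 counts in the MDA-MB-231 knockout. NAP1L3 had 16 counts in MCF-7 wild type and none in its knockout. In the other direction, the zinc-finger gene SALL2 and the F-box gene FBXL16 had no counts in the MDA-MB-231 knockout, against 22 and 14 in its wild type. ZNF141 and ZNF607 kept 1 count each in that knockout (ratios 74.7, counting interval 13.0 to 2991, and 52.2, interval 8.96 to 2102), and all 4 had higher values in the MCF-7 knockout than in its wild type. GABRP rose in MCF-7 and had 10 and 6 counts in MDA-MB-231 wild type and knockout.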

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

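The tests of the regions around EGR1 and EZH2, of an effect common to both lines, of a clone cultured more than once and of gene lists between the lines were chosen after the results were seen; the tests of reads from the other line, of the variance that windows account for, and of GC content, length and region for the sterol genes were written down before their results.

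All values here concern a difference of the knockout effect between the lines, tested as an interaction. The log2 fold change was more positive in MDA-MB-231 for 4571 genes and more negative there for 4324, which does not say in which line the effect was stronger. EGR1 differed by 0.33 and EZH2 by −0.60 on the log2 scale. Fitted differences were 11.3 for TGM2, 10.6 for NAP1L3, 10.0 for HDAC9, 9.19 for ZNF804A and 9.11 for SEC14L4, and −7.24 for SALL2, −6.46 for ZNF141, −6.38 for ZNF607, −6.37 for FBXL16 and −5.75 for GABRP. For all of these 10 genes but GABRP 1 group had 0 to 3 counts, so the fitted sizes depend on the prior count and bound nothing. As lists, the log2 fold change was more positive in MDA-MB-231 for DNA replication and S phase (adjusted p = 5.02e-08), NRF2 genes (2.22e-05), ribosome biogenesis (3.31e-05), respiratory chain (0.000223), proteases and inhibitors (0.00118), hypoxia and glycolysis (0.00118), mitosis (0.0117) and haematopoietic markers (0.0447). It was more negative there for the amino acid stress genes (3.54e-05) and the EZH2 neighbourhood (0.000845). These list tests used the preset correlation alone.

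EZH2 moved in opposite directions in the lines, while EGR1 rose in both. A shift of the chromosome 7 region may account for EZH2: it lay −0.072 from the median of its neighbours in MDA-MB-231 and −0.092 in MCF-7, inside their middle 50% in each line. For EGR1 the values argue against a regional shift as the whole source, since it exceeded its neighbours' median by 0.850 in MCF-7 and 1.34 in MDA-MB-231. It lay above their middle 50% and above 93.2% and 97.2% of them, so some neighbours rose more. The excess was more than 10 of its standard errors, which cover the spread between libraries and not that between genes. Copy number was not measured, and an effect of the deletion or of EGR1 on EZH2 itself stays open and untested.

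In MCF-7 69.7% of tested genes differed, and the effects did not go together between the lines. Reads of MDA-MB-231 cells are argued against, because of 45 genes abundant in that line and under 1 CPM in MCF-7 only 17 were higher in the MCF-7 knockout, with a median implied share of −0.0136%. Shifts of whole regions accounted for 4.76% of the variance of the fold changes, too little to be the whole source. Of 4036 shared calls 49.3% had 1 direction (exact 95% interval 47.8% to 50.9%, which takes genes as independent, and 46.9% to 52.7% with 1 library left out). These values argue against a common effect of the deletion on most of these genes, which would have given a larger share. A common effect on a part of the genes could leave the share near this value and stays open. Differences carried by 1 knockout clone cultured 2 times, or by clonal selection, cannot be told apart from the deletion: the SD between the knockout libraries was 0.925 times that between the wild-type libraries, and clone and genotype coincide. An effect of the deletion that is specific to each line stays open as well.

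Sterol and fatty acid synthesis genes fell in both lines, with list medians of −0.88 and −0.59. GC content and transcript length are argued against, since the medians were −0.87 in MCF-7 and −0.57 in MDA-MB-231 after their trend was removed, below the central 95% of matched random lists (−0.25 to 0.15 and −0.07 to 0.10). Regional shifts are argued against in the same way, with −0.77 and −0.52 after window medians were subtracted (random lists −0.22 to 0.16 and −0.07 to 0.08). An effect of the deletion stays open and untested. So do differences that came with clonal or puromycin selection, which coincide with genotype.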

How the results depend on the processing

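All alternatives for the counts and genes here were fixed before the data were examined; the lists with window medians subtracted were added afterwards. No paired analysis was possible in MCF-7 and for the interaction because the MCF-7 columns do not carry the replicate numbers of the labels, so the planned replicate block was not run there. The MDA-MB-231 columns carry 1 and 2, but libraries of the same number did not deviate together (Pearson −0.028 across genes, which are not independent replicates). With these numbers as a replicate block 2711 genes were higher and 2781 lower there, 1843 were called in both lines in a common direction, and 12 lists passed, without luminal markers (adjusted p 0.0671) and YAP and TEAD targets (0.0792); EGR1 (1.401) and EZH2 (−0.299) kept their calls. EGR1 and EZH2 kept direction and call in all alternatives, with ranges of 1.00 to 1.12 (MCF-7) and 1.38 to 1.43 (MDA-MB-231) for EGR1, 0.24 to 0.33 and −0.34 to −0.26 for EZH2, and 0.27 to 0.40 (largest adjusted p 0.0449) and −0.66 to −0.55 for their interactions; the other named genes did so too in 690 of 690 cases. The other named genes were chosen for large called changes in these same data, which favours kept calls and says little about other genes. Genes higher and lower in MCF-7 ranged from 4557 to 5641 and from 4927 to 5829, and in MDA-MB-231 from 2056 to 3139 and from 2025 to 3053. DESeq2 kept 80.5% and 86.3% of the calls in MCF-7 and 71.2% and 68.5% in MDA-MB-231, with none in the opposite direction. With 1 library left out, the lone library of a group being taken to vary like the others, counts were 4895 to 5209 higher and 5066 to 5294 lower in MCF-7, 1893 to 2994 and 1930 to 2900 in MDA-MB-231, and 8058 to 8898 for the interaction. Without MDA-MB-231 knockout library A the counts were 1893 and 1930, past 1.5 times from the 2889 and 2951 of all libraries, where fewer samples were fitted. Genes called in both lines in a common direction numbered 1301 with DESeq2 and 1274 at an adjusted p of 0.01, a stricter threshold, against 1991, and 1336 to 1923 with 1 library left out; the cause of the DESeq2 value was not tested. Without the low-count filter 885 genes were higher in both lines, against 659.2 expected (Fisher's exact p = 2.66e-25). That setting tested 23964 genes in both lines instead of 13615, and the added low-count genes can seldom be called. This lowers the expected number, so that p does not test the overlap. Genes higher in both lines numbered 576 against 527.4 expected with DESeq2 and 574 against 543.0 at an adjusted p of 0.01 (Fisher's exact p = 0.00412 and 0.0463). They numbered 811 against 755.3, 892 against 938.6 and 609 against 575.55 without MDA-MB-231 wild-type A, wild-type B and knockout A (Fisher's exact p = 0.00356, 0.983 and 0.0357), and genes lower in both 1031 against 1000.0 without wild-type B (Fisher's exact p = 0.0869). Gene lists past the threshold numbered 12 and 14, 15 and 17 without the low-count filter, and 11 to 14 and 13 to 15 with 1 library left out. With camera and an estimated correlation they numbered 0 and 0 (3 and 2 at an unadjusted p under 0.05), and with fry 26 and 8; the cause of the loss with an estimated correlation was not tested, and fry asks whether a list moves, not whether it moves more than other genes. Lists that did not pass with all libraries but did with 1 left out were, in MCF-7, classical Polycomb genes (adjusted p 0.0179, 0.0151 and 0.0183 without wild-type A, wild-type B and knockout A), haematopoietic markers (0.0311 and 0.0462 without wild-type B and knockout B) and oestrogen targets (0.0110 without knockout A), and in MDA-MB-231 DNA replication, interferon and cancer-testis genes (0.0110, 0.0357 and just under 0.05 without wild-type A), ribosome biogenesis (0.00369 and 0.0453 without wild-type B and knockout B) and respiratory chain (0.00121 without wild-type B). With window medians subtracted, 11 lists passed in MCF-7, against 13 without the subtraction in the same test, with the EGR1 neighbourhood (adjusted p 0.365) and hypoxia (0.0854) lost; classical Polycomb genes, which did not pass in the main test, passed both without (0.00506) and with the subtraction (0.0011), with 17 genes left of 24. In MDA-MB-231 11 passed, against 10, with the EZH2 neighbourhood lost (0.771) and ribosome biogenesis and homologous recombination genes gained (0.0366 each). The classical Polycomb, luminal, p53, YAP and TEAD and HLA lists of MDA-MB-231 had already been lost in that test without the subtraction (0.105, 0.0891, 0.0891, 0.304 and 0.0916), and histones passed (0.0128) with 4 genes left of 21. DESeq2 size factors moved the median log2 fold change by 0.0081 at most, and leaving out the low-count filter by 0.011. Small changes could be missed: on simulated data 27.1% of interactions of the smallest simulated size were recovered.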

Other observations

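All tests in this part were chosen after the data were seen.

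Neighbouring genes shifted together along several chromosomes in each line. In the MCF-7 knockout, 391 expressed genes of chromosome X had a median log2 fold change of −0.65, and 85.2% of them had a negative value. The first 40 Mb of chromosome 12 had a median of −0.52 (153 genes, and −0.13 over 166 genes in MDA-MB-231). Chromosome 18 beyond 50 Mb had −0.41 (57 genes) and chromosome 7 beyond 110 Mb 0.33 (172 genes). Among whole autosomes in MCF-7, the lowest medians were −0.21 on chromosome 16, −0.20 on 19 and −0.17 on 17. The highest were 0.23 on chromosome 5, which holds EGR1, 0.19 on 14 and 0.18 on 13. A trend on GC content was removed for the sterol list alone, so its part in these shifts was not tested. In the MDA-MB-231 knockout, chromosome 7 beyond 40 Mb had a median of −0.22 (447 genes, 86.1% with a negative value) against 0.09 for the first 40 Mb (142 genes). Chromosome 1 beyond 140 Mb had a median of −0.24 (519 genes, 88.2% with a negative value), and the first 40 Mb of chromosome 9 had 0.28 (120 genes, 90% with a positive value). Of 288 windows in MCF-7 28 were higher and 32 lower (adjusted p under 0.05 over shuffles), and of 287 in MDA-MB-231 37 were higher and 47 lower. Of these 21 passed in both lines, 10 in the same direction, such as chromosome 12 from 50 to 60 Mb (0.32 in MCF-7, 0.24 in MDA-MB-231), chromosome 13 from 40 to 50 Mb (0.35, 0.22) and chromosome 1 from 200 to 210 Mb (−0.27 in both), and 11 in opposite directions; the difference between the lines was not tested over windows. The SD of the window medians was 0.27 and 0.14. Between the knockout libraries it was 0.04 and 0.02, although 34 windows passed between the MCF-7 knockout libraries and 7 between its wild-type libraries, against none for either pair in MDA-MB-231. Across windows, knockout A against wild type A and knockout B against wild type B had Pearson values of 0.942 in MCF-7 and 0.923 in MDA-MB-231; windows are not independent replicates.

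Many zinc-finger genes of the ZNF family were higher in the MCF-7 knockout. The family was looked at because several members were among the genes that gained most, and these are included in the counts. Of 433 expressed ZNF genes 216 rose and 89 fell, with a median of 0.21. The 204 on chromosome 19 had a median of 0.28, against −0.30 for the 687 other expressed genes of that chromosome. ZNF genes on other chromosomes had a median of 0.20, so the rise was not particular to chromosome 19. With window medians subtracted, the median of the 431 ZNF genes with a window was 0.29. In MDA-MB-231, 30 of 365 expressed ZNF genes rose and 70 fell (median −0.04). Since the family was chosen from these values, no test of it is given, and the difference between the lines was not tested.

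Library composition differed between the lines and, for some classes, between genotypes. Replication-dependent histone genes took 0.0551% to 0.0588% of counts in the MCF-7 libraries, and in MDA-MB-231 0.0062% and 0.0063% in wild type against 0.0093% and 0.0083% in knockout. Ribosomal RNA genes took 0.523% and 0.572% in MCF-7 wild type, 0.773% and 0.735% in MCF-7 knockout, and 0.0433% to 0.0547% in MDA-MB-231. The 10 most abundant genes took 4.65% to 5.58% of counts in the 8 libraries.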
